A study of Mus musculus with 7 samples.

How the data were processed

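Ventricles were isolated from mouse embryos of mixed background at E11.5 and kept in an RNA-stabilising solution, and polyadenylated RNA was sequenced. The submitters' processing notes name STAR 2.4.2a, featureCounts, Subread 1.5.0, edgeR and the mm10 genome. The settings, the gene annotation and the use of strand are not stated in the sources used here. The deposited table holds the authors' raw read counts per gene in 7 libraries, with gene coordinates and summed exon length. It also holds the authors' log2 fold changes, p-values and false discovery rates for the knockout against the Cre controls. Across genes these log2 fold changes correlated at r = 1.00 with an edgeR fit of the same 5 libraries made here. The deposited counts cover 13701 genes, with a lowest count summed over the libraries of 9 and no mitochondrial gene, so genes below that were not analysed here.

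Notes were removed from 47 gene names, and 20 names that had turned into dates were given their symbols back from coordinates in the annotation. Of 13211 symbols found in the annotation, 99.9% lay on an overlapping span. GC content was that of the longest annotated transcript, found for 96.4% of the genes, and the others were given the median. Gene length was the deposited summed exon length.

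Groups came from the genotype labels: Hand1 knockout (2 libraries), flox control (2) and Cre control (3). Total counts were 28346700 and 18975283 in knockout replicates 1 and 2, and 24343222 and 25969446 in flox control replicates 1 and 2. They were 25577174, 28152695 and 25634969 in Cre control replicates 1 to 3. Genes near 1 CPM therefore rest on few counts and carry more counting error.

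The test was edgeR 4.0.16 quasi-likelihood (TMM scaling, filterByExpr, robust estimation) in R 4.3.3. All 7 libraries were fitted in 1 model with a mean per group, and 13695 genes were tested. The threshold was a Benjamini-Hochberg adjusted p below 0.05. CPM values were TMM-scaled, and log2 CPM used a prior count of 2. DESeq2 1.42.0 gave no adjusted p for 1 gene. Limma 3.58.1 was used for voom, camera and fry. The 37 gene lists were tested with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. Lists with fewer than 3 measured genes were not tested. Without scaling factors the median of all genes moved to -0.11 (log2) against flox controls and -0.10 against Cre controls, and changes reported here are relative to the TMM scale.

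The groups, comparisons, gene lists and named-gene rule were fixed before the data were examined. The rule took Hand1, Hand2 and Nkx2-5. It then took up to 10 called genes each way per comparison with the knockout, and 5 each way between the controls, by log2 fold change. These needed a mean of at least 5 CPM, a symbol that is not a predicted gene and no overlap between the groups. From each list it took members by adjusted p or, where none passed, by mean CPM. Since edgeR called at most 3 genes per comparison, the rule was applied to the DESeq2 calls and, between the controls, to the edgeR calls of the control libraries alone. Both steps, and the list members named from DESeq2 calls, were chosen after the values were seen.

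Alternatives fixed before the data were examined were RLE scaling, no scaling factors, DESeq2, limma-voom, edgeR without robust estimation, and other filters on low counts. The others were fits of the compared groups alone, all 5 controls as 1 group, and leaving out each library, erythroid genes or sex-linked genes. Embryo sex as a covariate, and the libraries whose identifiers start with NT alone, completed this set. Added after seeing the data were the edgeR likelihood ratio test, voom with sample quality weights, corrections for gene length and GC content, DESeq2 and camera with an estimated correlation without knockout replicate 2, DESeq2 without each library in turn, camera between the controls without each library in turn, and edgeR on the control libraries alone without each of them. The corrections used smooth trends per library from mgcv 1.9.3.

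The tests were run on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. With undistorted libraries edgeR recovered 76% of 2-fold and 99% of 4-fold changes against flox controls, and DESeq2 81% and 100%. Knockout replicate 2 was then given the length and GC trend of the real library and random variation per gene. That variation matched its remaining spread beyond that of the controls. With both, edgeR recovered 0% and 37% against flox controls, and DESeq2 42% and 83%. The effects of the trend and of the added variation were not separated. In these libraries DESeq2 called 136 genes against both groups, of which 12 had not been changed in the simulation. Against single groups the share was larger, with 20 of 145 calls against flox and 52 of 191 against Cre not changed. With undistorted libraries these counts were 35 of 216 and 34 of 220.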

Results

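Polyadenylated RNA was measured by sequencing in dissected ventricles of mouse embryos at E11.5. The question was how gene expression changes in hearts that lose Hand1, a basic helix-loop-helix transcription factor of the developing left ventricle. Hand1 knockout hearts (2 libraries) were homozygous for floxed Hand1 and carried a Cre allele at Nkx2-5. Flox controls (2 libraries) were homozygous for floxed Hand1 and had no Cre. Cre controls (3 libraries) carried the Cre allele with wild-type Hand1. Total counts lay between 18975283 (knockout replicate 2) and 28346700 (knockout replicate 1), over 13701 genes. The labels give each library an identifier of its own and say nothing of litters, so the p-values measure the spread between these samples.

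Hand1 was nearly absent from both knockout libraries. It lies on chromosome 11 from 57828713 to 57832147 on the minus strand (mm10) and has 2 exons. It was counted 37 and 19 times in knockout replicates 1 and 2. The counts were 875 and 1272 in flox control replicates 1 and 2, and 2465, 1852 and 2189 in Cre control replicates 1 to 3. On the CPM scale (counts scaled to library size), Hand1 stood at 1.22 ± 0.104 (SD, n = 2) in the knockout, 40.9 ± 9.53 (SD, n = 2) in flox controls and 81.2 ± 14.2 (SD, n = 3) in Cre controls. The knockout mean was 2.98% of the flox control mean and 1.5% of the Cre control mean. The log2 change was -5.06 ± 0.31 (SE) against the flox controls (edgeR adjusted p = 0.0363) and -6.05 ± 0.32 against the Cre controls (edgeR adjusted p = 0.00948). By DESeq2 the adjusted p-values were 1.16e-38 and 1.09e-64. The edgeR call against the flox controls was lost without any 1 of the 5 control libraries: flox control replicate 1 (adjusted p = 0.128) or 2 (0.203), or Cre control replicate 1 (0.168), 2 (0.16) or 3 (0.386). The call against the Cre controls was lost without Cre control replicate 1 (adjusted p = 0.0817), 2 (0.071) or 3 (0.117). Cre controls are not part of the comparison with flox. Without Cre control replicate 1, 2 or 3 the log2 change of Hand1 against flox stayed at -5.056, -5.035 and -5.035. Those calls were therefore lost through the error of the test, which rests on all groups, and not through a smaller change. The flox controls held 50.3% of the Hand1 level of the Cre controls. That difference did not pass the edgeR test with all 7 libraries (adjusted p = 0.906) or with the 5 control libraries alone (adjusted p = 0.101).

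Nkx2-5, a homeobox factor of the early heart whose locus holds the Cre allele, lies on chromosome 17 from 26838665 to 26841565. It stood at 107 ± 25.6 CPM (SD, n = 2) in the knockout, 146 ± 20.9 (SD, n = 2) in flox controls and 100 ± 12.8 (SD, n = 3) in Cre controls. No comparison of Nkx2-5 passed the edgeR test with all libraries (adjusted p = 0.606 against flox, 0.812 against Cre and 0.999 between the controls). Without knockout replicate 1 it was lower in the knockout than in the flox controls (log2 -0.72, edgeR adjusted p = 0.0197). Hand2, the paralog of Hand1 that is prominent in the right ventricle, lies on chromosome 8 from 57320983 to 57324517. It stood at 159 ± 25.8, 156 ± 19.0 and 171 ± 4.90 CPM in knockout, flox control and Cre control hearts. It passed no edgeR test (adjusted p = 0.964 against flox and 0.755 against Cre).

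**Figure D1:**
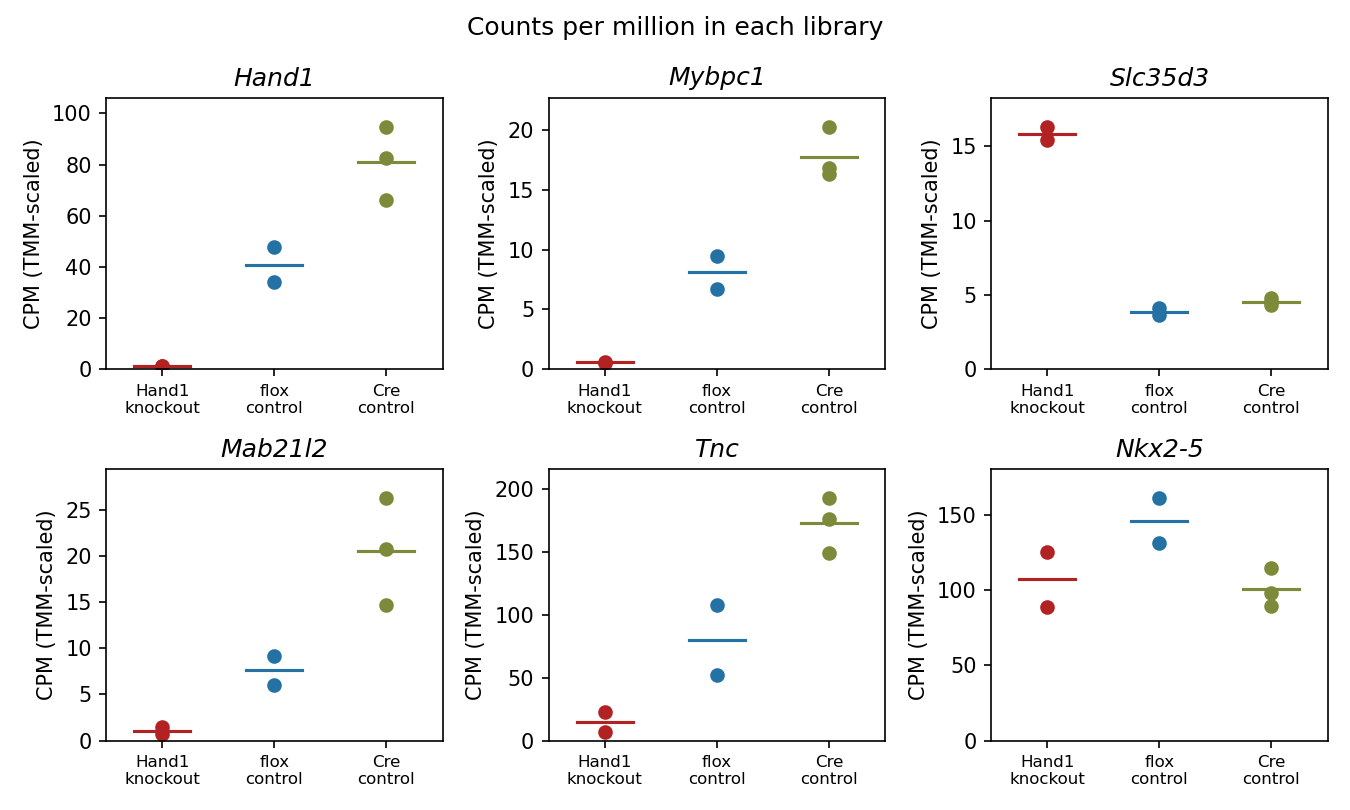
CPM (TMM-scaled, vertical axes starting at 0) of 6 genes in each of the 7 libraries, where points are libraries and horizontal lines are group means. Hand1 and Mybpc1 were at most 1.29 and 0.593 CPM in the knockout libraries, and Slc35d3 was 16.3 and 15.4 CPM there against at most 4.80 CPM in the controls.

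Knockout replicate 2 stood apart from the other 6 libraries. Its Pearson correlation across genes with any other library was at most 0.927, whereas each of the others reached at least 0.978 with its closest library. Genes are not independent replicates in these correlations. The first principal component held 70.1% of the variance and placed this library at 110.8 and the others between -31.4 and 12.1. In knockout replicate 2 the 1370 shortest genes (median length 893.5 bases) lay above the controls by a median of 1.15 (log2), and the 1370 longest (median 8009 bases) lay at -0.67. In knockout replicate 1 the same groups lay at 0.05 and -0.30. Myh7, the beta-myosin heavy chain, lay at 0.37 in replicate 1 and -2.77 in replicate 2 relative to the control mean, and Fn1, fibronectin, lay at 0.08 and -3.11. Vcan, a transcript of 14689 bases, lay at -0.58 in replicate 1 and -0.64 in replicate 2. Counts of Xist and 4 Y-linked genes marked both knockout libraries, flox control replicate 2 and Cre control replicate 2 as female and the other 3 libraries as male.

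**Figure D2:**
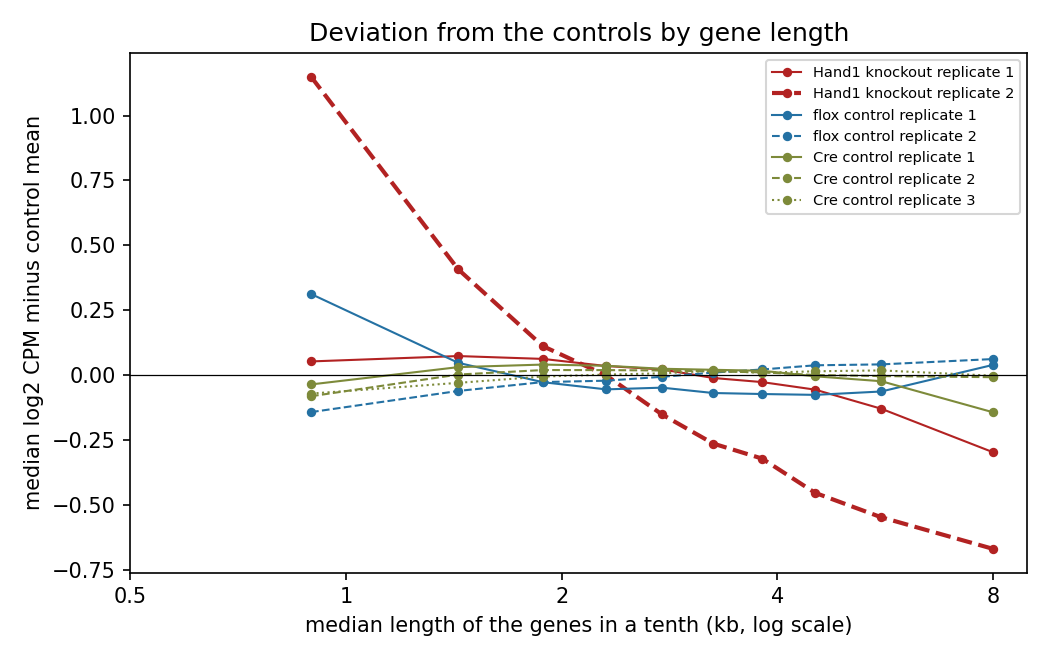
Median log2 CPM of each library minus the mean of the control libraries (for a control library, of the other 4), for genes sorted by length into 10 groups; the horizontal axis gives the median length of each group in kilobases on a log scale. Knockout replicate 2 runs from 1.15 in the shortest group to -0.67 in the longest, and the group medians of the other libraries stay between -0.30 and 0.31.

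Against both control groups, Hand1 and Mybpc1 fell in the edgeR quasi-likelihood test, and no gene rose. Mybpc1 encodes slow-type myosin-binding protein C of the sarcomere and lies on chromosome 10 from 88518279 to 88605152. It stood at 0.568 ± 0.0364 CPM (SD, n = 2) in the knockout, 8.09 ± 1.90 (SD, n = 2) in flox controls and 17.8 ± 2.15 (SD, n = 3) in Cre controls. Its log2 change was -3.81 ± 0.28 (SE, edgeR adjusted p = 0.0473) against flox and -4.95 ± 0.28 (edgeR adjusted p = 0.00948) against Cre. Against the mean of both control groups edgeR called 3 genes, Hand1, Mybpc1 and Slc35d3. Slc35d3, of the nucleotide-sugar transporter family, lies on chromosome 10 from 19847917 to 19851459 and rose by 1.91 ± 0.14 (log2, SE, edgeR adjusted p = 0.0324), above every control in 2 of 2 knockout libraries. At an unadjusted p under 0.05 edgeR found 1145 genes against flox, 2110 against Cre and 2173 against the mean of both. The counts changed when single libraries were left out. Without knockout replicate 1, edgeR called 7200 genes against both groups and 8568 against their mean, and without knockout replicate 2 it called 19 and 47. Without flox control replicate 1 these counts were 0 and 2. Without flox control replicate 2, or without Cre control replicate 1, 2 or 3, both counts were 0. A knockout group of 1 library is assumed to vary like the other groups.

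DESeq2 called 169 genes against both control groups in the same direction, 132 lower and 37 higher, and 1 gene in opposite directions. Lower genes included Mab21l2, a nuclear developmental regulator, Tnc, the matrix glycoprotein tenascin C, and Smoc1, a secreted calcium-binding matrix protein. Mab21l2 stood at 1.06 ± 0.568 CPM (SD, n = 2) in the knockout, 7.59 ± 2.29 (SD, n = 2) in flox controls and 20.6 ± 5.76 (SD, n = 3) in Cre controls. Its DESeq2 log2 changes were -2.76 ± 0.51 (SE, adjusted p = 3.08e-05) and -4.20 ± 0.47 (adjusted p = 7.80e-16), while edgeR gave adjusted p = 0.295 and 0.116. Tnc stood at 14.5 ± 11.2, 80.0 ± 39.1 and 173 ± 21.8 CPM in the same groups (DESeq2 adjusted p = 0.00873 and 1.83e-07, edgeR adjusted p = 0.415 and 0.177). The kinase gene Hipk2, the lectin-pathway protease gene Masp1, the metalloproteinase gene Mmp28 and Smoc1 had DESeq2 log2 changes between -2.36 and -1.98 in both comparisons. Psd, an exchange factor for ARF6, had -2.11 against flox and -3.48 against Cre, and the ubiquitin ligase gene Cbl had -2.41 and -1.80. Without knockout replicate 1 the changes became -3.58 and -4.69 for Tnc, -3.49 and -4.93 for Mab21l2 and -2.68 and -2.82 for Mmp28. Without knockout replicate 2 they became -1.82 and -2.93 for Tnc and -3.09 and -2.47 for Cbl. The call against flox was lost for Tnc without flox control replicate 2 (log2 -1.81, adjusted p = 0.881), and for Psd and Cbl without flox control replicate 1 (0.114 and 0.199). For Mmp28 it was lost without flox control replicate 1 (0.0805) or 2 (0.81) or Cre control replicate 1 (0.0703) or 3 (0.0578). The call of Cbl against Cre was lost without Cre control replicate 2 (0.124) or 3 (0.131). With Hand1 and Mybpc1, these are the 10 decreases that the rule for named genes gives when it is applied to the DESeq2 calls, a step chosen after the values were seen.

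The 10 increases by the same step included Cck, the peptide hormone cholecystokinin, Tnni2, fast skeletal troponin I, and Scn10a, a voltage-gated sodium channel. Cck was 9.22-fold higher than in flox controls and 6.06-fold higher than in Cre controls (log2 3.20 ± 0.44 and 2.60 ± 0.39, DESeq2 adjusted p = 6.28e-10 and 1.63e-08). Slc35d3 was 4.19-fold and 3.55-fold higher, Tnni2 3.22-fold and 3.84-fold, and Scn10a 2.15-fold and 2.89-fold. Stard10, a lipid transfer protein, was 3.11-fold and 5.55-fold higher, and Rxfp1, the relaxin receptor, 3.70-fold and 2.85-fold. Apold1, an endothelial early-response gene, was 1.95-fold and 3.41-fold higher, and it also differed between the control groups. Hfe2, which encodes hemojuvelin, was 2.86-fold and 2.30-fold higher, and Lrrc3b 2.98-fold and 1.97-fold. Hist1h2ak belongs to a histone family whose members share reads, so its value is uncertain. It stood at 4.92 and 32.1 CPM in knockout replicates 1 and 2 and at no more than 0.749 CPM in the controls. Without knockout replicate 2, Stard10 had log2 changes of 0.97 and 1.81. Against flox, Cck had 3.82 without flox control replicate 2 and Rxfp1 had 2.60 without flox control replicate 1. Without any 1 of the 5 controls the calls against flox were lost for Scn10a (adjusted p from 0.227 to 0.999), Stard10 (0.0834 to 0.721) and Apold1 (0.268 to 0.79). Without flox control replicate 2 they were lost for Tnni2 (0.329), Hfe2 (0.258) and Lrrc3b (0.12). The calls against Cre were lost for Rxfp1 without Cre control replicate 1 (0.133), 2 (0.0923) or 3 (0.123), and for Hfe2 without Cre control replicate 1 (0.121) or 3 (0.163). For Lrrc3b the call against Cre was lost without any 1 of the 5 controls (0.0562 to 0.286) or knockout replicate 2 (0.105). Of these 10 genes edgeR called Slc35d3 against the mean of both groups and none of the others in any comparison with all 7 libraries (adjusted p of Cck 0.214 and 0.129).

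The DESeq2 genes followed gene length in part. Those called lower had a median length of 5098 bases and those called higher 1882 bases, against 2993 bases for all genes tested. With factors for gene length and GC content, added after seeing the data, 84 of the 169 genes were still called against both groups. So were 18 of the 20 named genes, all except Psd and Tnni2, whose calls against flox were lost. Psd went from -2.11 ± 0.41 (SE) to -1.57 ± 0.53 (adjusted p = 0.0899), with a smaller change and a larger error, and Tnni2 went from 1.69 ± 0.37 to 1.11 ± 0.37 (adjusted p = 0.0815), with a smaller change. With these factors Hipk2 went to -1.55 against flox (adjusted p = 0.0448) and -1.38 against Cre (adjusted p = 0.034), and Scn10a to 1.80 and 2.38. Against Cre, Tnc went to -2.95, Psd to -2.79 and Tnni2 to 1.26. Without knockout replicate 2, DESeq2 called 232 genes against both groups, among them 108 of the 169 and 19 of the 20 named ones, all except Lrrc3b. Without knockout replicate 1 it called 6877, among them 162 of the 169. Without flox control replicates 1 and 2 in turn it called 20 and 33, with 20 and 20 of the 169. Without Cre control replicates 1 to 3 in turn it called 34, 29 and 29, with 33, 29 and 28 of the 169. The fit with knockout replicate 2 as the only knockout library called so many genes that keeping most of the 169 tells little. Independent lists of the sizes called with all 7 libraries would share 5.13 lower and 1.47 higher genes. Libraries simulated with no group effect, 5 times per setting, shared a median of 0 and at most 2. In them each gene varied independently between libraries around the mean of the controls. Structure shared between the real libraries was not simulated, so these values do not bound what it could give. Both comparisons used the same knockout libraries, so the lists are not independent.

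**Figure D3:**
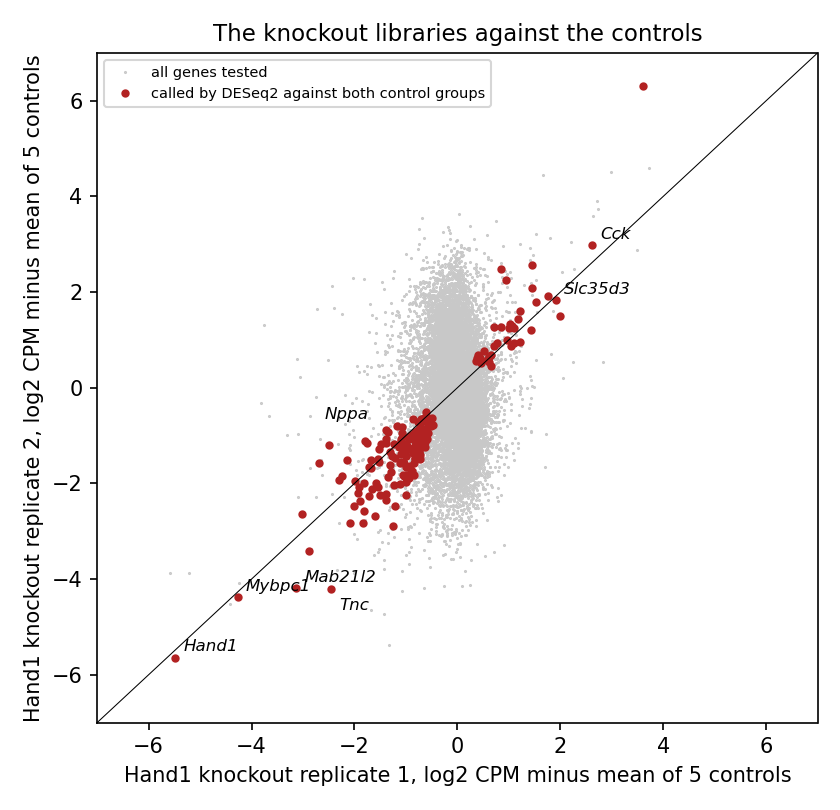
Log2 CPM of each gene in knockout replicate 1 (horizontal axis) and knockout replicate 2 (vertical axis) minus the mean of the 5 control libraries, with the line of equality. Grey points are all genes tested, spread more widely along replicate 2, and red points are the 169 genes that DESeq2 called against both groups, each on the same side of 0 in both libraries.

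The comparison of knockout with flox controls holds floxed Hand1 constant, and the groups differ by the Cre allele and by recombination. A call in this comparison alone therefore does not separate loss of Hand1 from the Cre allele. Beyond the genes above, DESeq2 placed Cacna1d, an L-type calcium channel, and Kcnd3, a potassium channel, lower in the knockout (log2 -1.71 and -1.69, adjusted p = 1.45e-07 and 3.79e-04). Myl7, the atrial myosin light chain, was higher (log2 1.20, adjusted p = 0.0145). Tnnt1, slow skeletal troponin T, stood at 63.9 ± 7.23 CPM (SD, n = 2) against 124 ± 13.1 (SD, n = 2) in flox controls and was lower (log2 -0.93, DESeq2 adjusted p = 0.00214). In Cre controls Tnnt1 stood at 61.3 ± 6.27 CPM (SD, n = 3) and was also lower than in flox controls (log2 -1.03, edgeR adjusted p = 0.0273, control libraries alone), a call lost without any 1 Cre control. DESeq2 called 301 genes in all, 92 higher and 209 lower, and edgeR called 2 of 13695. The edgeR count was 7547 without knockout replicate 1, 46 without knockout replicate 2 and 0 without flox control replicate 1 or 2 or Cre control replicate 1, 2 or 3. DESeq2 called 7201 genes without knockout replicate 1, 972 without knockout replicate 2, 30 and 42 without flox control replicates 1 and 2, and 57, 54 and 58 without Cre control replicates 1 to 3. The DESeq2 call of Kcnd3 was lost without flox control replicate 1 (adjusted p = 0.209) or 2 (0.379). The calls of Myl7 and Tnnt1 were lost without any 1 of the 5 controls (0.223 to 0.999 and 0.207 to 0.79). With length and GC factors Kcnd3 went from -1.69 ± 0.35 (SE) to -1.08 ± 0.42 (adjusted p = 0.191), and Myl7 from 1.20 ± 0.32 to 0.43 ± 0.21 (adjusted p = 0.384). Both calls were lost through a smaller change, for Kcnd3 with a larger error, and Cacna1d went to -1.0 (adjusted p = 7.63e-04).

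The comparison of knockout with Cre controls holds the Cre allele constant. By DESeq2 the knockout was lower for Isl1, a factor of the second heart field (log2 -2.45, adjusted p = 0.00410), and for the growth factor gene Bmp4 (log2 -1.31, adjusted p = 0.00327). The secreted Wnt antagonists Sfrp2 and Sfrp5 were lower (log2 -2.53 and -2.40, adjusted p = 4.58e-04 and 0.00271), as was the potassium channel gene Kcnk3 (log2 -1.74, adjusted p = 3.85e-05). Higher genes included Fhl2, a LIM-domain protein of the sarcomere (log2 0.83, adjusted p = 1.99e-06), the homeobox gene Irx2 (log2 0.81, adjusted p = 0.00366) and the retinaldehyde dehydrogenase gene Aldh1a1 (log2 1.09, adjusted p = 0.00325). DESeq2 called none of these 8 genes against flox controls. Between the control groups none of the 8 passed the edgeR test on the control libraries alone (adjusted p from 0.163 for Isl1 to 0.564 for Aldh1a1). A miss in edgeR, which called fewer genes than DESeq2, does not show that the control groups were alike. A difference particular to the Cre controls therefore stays open for these genes. DESeq2 called 555 genes, 219 higher and 336 lower, and edgeR called 2. In the authors' deposited table of this comparison 1439 genes had a false discovery rate below 0.05, 931 higher and 508 lower. Of these, 460 were called by DESeq2 against Cre controls and 132 against both groups. The edgeR count was 8813 without knockout replicate 1, 63 without knockout replicate 2 and 0 without Cre control replicate 1, 2 or 3. DESeq2 called 8395 genes without knockout replicate 1, 257 and 251 without flox control replicates 1 and 2, and 136, 143 and 104 without Cre control replicates 1 to 3. Without knockout replicates 1 and 2 in turn, the log2 change was -1.80 and -3.52 for Isl1 and -3.90 and -1.77 for Sfrp5, and it was -3.20 for Sfrp2 without knockout replicate 1. Calls were lost without Cre control replicate 3 for Isl1 (adjusted p = 0.113), and without Cre control replicates 1 and 3 for Bmp4 (0.121 and 0.138) and Sfrp5 (0.059 and 0.076). That of Fhl2 was lost without Cre control replicate 1, 2 or 3 (0.0629 to 0.185), and that of Irx2 without any 1 of the 5 controls (0.105 to 0.348). That of Aldh1a1 was lost without flox control replicate 1 or 2 or Cre control replicate 2 or 3 (0.0597 to 0.222).

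The control groups differ by the Cre allele and by the floxed alleles. On the 5 control libraries alone, edgeR called 56 genes, 14 higher and 42 lower in Cre controls. Eno2, the neuronal enolase, stood at 36.9 ± 12.4 CPM (SD, n = 2) in flox controls and 6.07 ± 0.275 (SD, n = 3) in Cre controls (log2 -2.61 ± 0.20, SE, edgeR adjusted p = 0.00856). Lyz2, a macrophage lysozyme (44.0 against 7.29 CPM), the grainyhead factor gene Grhl1 (39.5 against 9.19 CPM), Hist3h2a (28.2 against 8.76 CPM) and Rpl14-ps1 (24.7 against 4.56 CPM) were also lower in Cre controls. Rpl14-ps1 is a pseudogene, Lyz2 has a close paralog and Hist3h2a belongs to a histone family, so shared reads make their values uncertain. Higher in Cre controls were Cadm1, a cell adhesion molecule (70.4 against 28.5 CPM, log2 1.30 ± 0.11, edgeR adjusted p = 0.00856), and Padi2 (18.2 against 7.09 CPM). Col22a1 (9.20 against 2.70 CPM), Ccdc88c (12.8 against 4.69 CPM) and Grhl3 (7.82 against 2.98 CPM) were higher as well. These 10 genes were named from the control libraries alone, a step chosen after the values were seen. At 24 of the 56 genes both knockout libraries lay nearer the flox controls, at 10 nearer the Cre controls, and at 22 they were split. With all 7 libraries edgeR called 0 genes, with 428 at an unadjusted p under 0.05, and DESeq2 called 73. These included Mybpc1 and Psd, higher in Cre controls (log2 1.14 and 1.37, DESeq2 adjusted p = 0.0103 and 0.00923). Apold1 was lower in Cre controls (log2 -0.81, DESeq2 adjusted p = 0.0311). Without knockout replicate 1 or 2 edgeR called 56 and 57, and DESeq2 363 and 358. Without flox control replicates 1 and 2 in turn DESeq2 called 32 and 11, and without Cre control replicates 1 to 3 it called 18, 21 and 17. On the control libraries alone edgeR called 237 and 4122 genes without flox control replicates 1 and 2, with all 10 named genes in both. Without Cre control replicates 1 to 3 in turn it called 0, 4 and 0, and the 4 included Hist3h2a, Lyz2 and Rpl14-ps1.

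Gene lists of the heart, its pathways and the cell types of a dissected ventricle were tested with camera. Against flox controls, 4 of 36 lists passed with the preset correlation and 0 with an estimated one. Oxidative phosphorylation was higher (53 genes, median log2 0.73, adjusted p = 6.44e-10, and adjusted p = 0.713 with an estimated correlation). Cardiac jelly and extracellular matrix (27 genes, median -0.49, adjusted p = 7.38e-04), the Wnt pathway (25 genes, median -0.43, adjusted p = 0.00506) and cushion and valve mesenchyme (22 genes, median -0.44, adjusted p = 0.00506) were lower. Each of these had adjusted p = 0.713 with an estimated correlation. Against Cre controls the same 4 lists passed, with medians of 0.80, -0.68, -0.53 and -0.74 (adjusted p = 3.85e-08, 5.81e-04, 7.99e-04 and 0.0014). Outflow tract and second heart field (14 genes, median -0.62, adjusted p = 0.0214), erythroid cells (21 genes, median -0.51, adjusted p = 0.0214) and megakaryocytes and platelets (13 genes, median -1.32, adjusted p = 6.26e-04) were lower too. With an estimated correlation the adjusted p was 0.688 for each of these 7 lists.

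The 4 lists that passed in both comparisons lay further from the controls in knockout replicate 2 than in replicate 1. The median gene length was 868 bases for oxidative phosphorylation, 5893 for the matrix list, 3573 for the Wnt list and 3428.5 for the mesenchyme list, against 2993 for all genes tested. Relative to the controls, the oxidative phosphorylation, matrix, Wnt and mesenchyme lists lay at medians of 0.15, -0.09, -0.09 and -0.26 in knockout replicate 1 and at 1.17, -1.87, -1.16 and -1.08 in knockout replicate 2. Without knockout replicate 2 none of the 4 passed against flox controls (adjusted p = 0.0523, 0.721, 0.923 and 0.506). Against Cre controls the oxidative phosphorylation, matrix and mesenchyme lists still passed and the Wnt list did not (adjusted p = 1.56e-04, 0.0191, 0.00792 and 0.299). The Wnt list was also lost against flox without flox control replicate 2 (adjusted p = 0.0938). The outflow tract, erythroid and megakaryocyte lists lay at -0.36, -0.57 and -0.64 in knockout replicate 1 and at -0.80, -0.01 and -0.86 in replicate 2. Against Cre controls these 3 lists still passed without knockout replicate 2 (adjusted p = 0.00173, 7.06e-06 and 2.54e-05) and did not pass without replicate 1 (0.218, 0.833 and 0.204). The erythroid list was also lost without Cre control replicate 3 (0.154). Without knockout replicate 2 camera called 6 lists against flox and 12 against Cre, including glycolysis, higher in both comparisons (adjusted p = 1.61e-08 and 8.85e-06), and 0 and 0 with an estimated correlation. Without knockout replicate 1 it called 7 lists against flox, and without flox control replicate 1 it called 8. Single genes of the 4 lists called by DESeq2 against both groups were Tnc, Vcan and Nkd2. Vcan, the proteoglycan versican, stood at 987 ± 27.3 CPM (SD, n = 2) in the knockout against 1646 ± 6.93 (SD, n = 2) in flox controls and 1415 ± 43.8 (SD, n = 3) in Cre controls. Nkd2, a Wnt antagonist, had DESeq2 log2 changes of -0.79 and -0.72. The DESeq2 calls of Vcan were lost without any 1 of the 5 controls (adjusted p from 0.441 to 0.999 against flox and 0.264 to 0.495 against Cre). Those of Nkd2 were lost without any 1 of the 7 libraries (0.0546 to 0.999 and 0.0825 to 0.438). With length and GC factors both genes lost both calls as the errors grew and, except for Vcan against Cre, the changes shrank. Vcan went from -0.71 ± 0.12 (SE) and -0.49 ± 0.11 to -0.40 ± 0.28 and -0.60 ± 0.26 (adjusted p = 0.621 and 0.169), and Nkd2 from -0.79 ± 0.23 and -0.72 ± 0.21 to -0.59 ± 0.34 and -0.38 ± 0.31 (0.501 and 0.515). Adjusted over the list alone edgeR called 0 of these genes against flox and 1 matrix gene against Cre, and over all genes 0. At an unadjusted p under 0.05 there were 6 and 27 oxidative phosphorylation genes, 3 and 4 matrix genes, 4 and 5 Wnt genes and 7 and 7 mesenchyme genes. DESeq2 called 1 and 4, 2 and 3, 1 and 4 and 1 and 2 genes of these lists. With length and GC factors the oxidative phosphorylation call against flox, Cyc1, was lost (DESeq2 adjusted p = 0.204). Against Cre, Cox5a (0.847), Cox7a1 (0.0677) and Cox7a2 (0.0916) lost their calls, and Cox7b kept its call (1.96e-04).

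**Figure D4:**
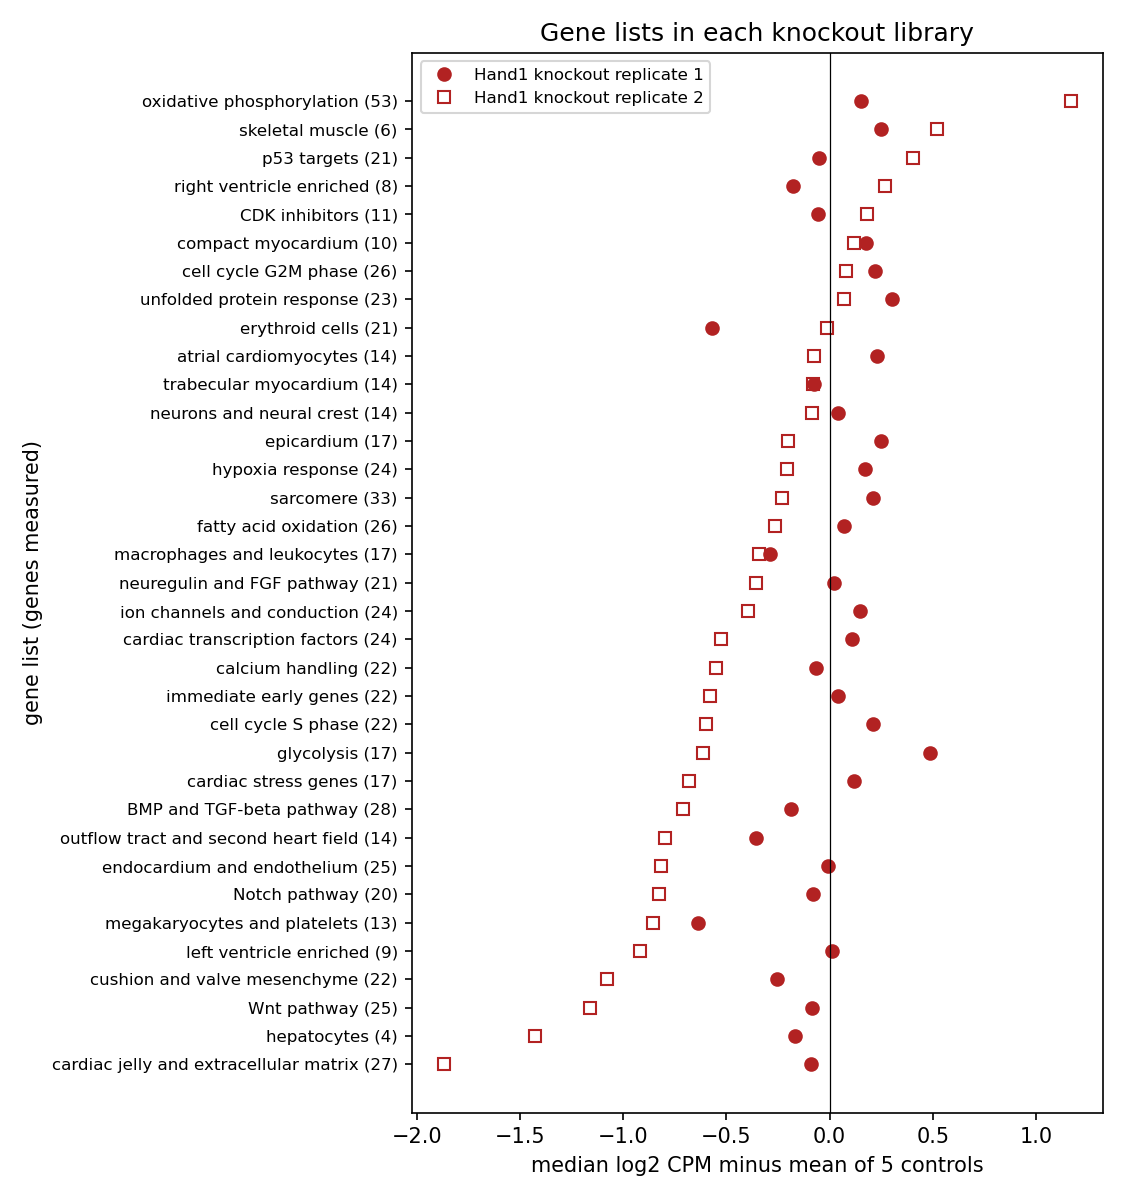
Median log2 CPM of each gene list minus the mean of the 5 control libraries (horizontal axis) in knockout replicate 1 (filled circles) and knockout replicate 2 (open squares). The number of genes measured stands beside each list. Lists with fewer than 3 measured genes and the embryo sex list are left out. Replicate 2 ranges from -1.87 for the matrix list to 1.17 for oxidative phosphorylation, and replicate 1 from -0.64 for megakaryocytes and platelets to 0.49 for glycolysis.

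Genes of ventricular identity included several DESeq2 calls. Nppa, the atrial natriuretic peptide of trabecular myocardium, stood at 614 ± 130 CPM (SD, n = 2) in the knockout against 1389 ± 176 (SD, n = 2) in flox controls and 1307 ± 116 (SD, n = 3) in Cre controls. Its DESeq2 log2 changes were -1.15 (adjusted p = 6.74e-04) and -1.07 (adjusted p = 2.75e-04), and edgeR gave adjusted p = 0.369 and 0.25. Slit2, an axon guidance ligand, was lower in both comparisons by DESeq2 (log2 -1.03 and -0.90). Cck and Hand1 are members of the right and left ventricle lists. The trabecular genes did not move one way against Cre. There DESeq2 called Nppa, Slit2 and Cited1 (log2 -0.94) lower, and Hopx (1.09), Smpx (2.08) and Fhl2 (0.83) higher. The call of Smpx was lost with length and GC factors (DESeq2 adjusted p = 0.0588). The calls against flox were lost without any 1 of the 5 controls for Nppa (adjusted p from 0.0795 to 0.722) and Slit2 (0.081 to 0.999). Against Cre they were lost without any 1 Cre control for Nppa (0.0801 to 0.129) and any 1 of the 5 controls for Slit2 (0.138 to 0.339). With length and GC factors Nppa went to -1.66 against Cre, and the call of Slit2 against flox was lost as its change went from -1.03 ± 0.29 (SE) to -0.66 ± 0.26 (adjusted p = 0.203). Over all genes edgeR called Hand1 alone among 24 cardiac transcription factors and 9 left ventricle enriched genes, and 0 of 14 trabecular, 10 compact and 8 right ventricle enriched genes. Adjusted over the list alone edgeR called, against flox and Cre, 1 and 1 cardiac transcription factors, 2 and 5 left ventricle, 0 and 7 trabecular, 0 and 0 compact and 1 and 2 right ventricle genes. At an unadjusted p under 0.05 there were 4 and 8 trabecular, 0 and 2 compact and 3 and 3 right ventricle genes. DESeq2 called 2 and 6 trabecular genes, 1 and 2 right ventricle genes, and 0 and 1 compact gene, Tcf21, whose call was lost without any 1 of the 5 controls or knockout replicate 2 (0.344 to 0.558), and with length and GC factors (log2 0.46 ± 0.15 to 0.09 ± 0.18, adjusted p = 0.819). The medians of the 5 lists against flox were -0.23 for transcription factors, -0.11 for left ventricle, 0.08 for trabecular, 0.16 for compact and 0.03 for right ventricle. None of these lists passed camera. Fry, which tests whether the genes of a list move one way on balance, called the left ventricle list lower (adjusted p = 0.00809 against flox and 0.00379 against Cre), and this list contains Hand1.

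Contractile and electrical genes were called singly. Cacna1d stood at 11.2 ± 2.20 CPM (SD, n = 2) in the knockout against 37.6 ± 6.84 (SD, n = 2) in flox controls and 39.3 ± 2.81 (SD, n = 3) in Cre controls. Against both groups DESeq2 called the potassium channel genes Kcnd3 and Kcnj12 lower and Scn10a higher, Stard10 of the atrial list higher, and Nppa and Tnc of the cardiac stress list lower. The calls of Kcnj12 were lost without knockout replicate 2 or any 1 of the 5 controls (adjusted p from 0.0667 to 0.999 against flox and 0.137 to 0.345 against Cre). That of Kcnd3 against Cre was lost without any 1 of the 5 controls (0.0633 to 0.273), and those of Cacna1d held without each of the 7 libraries in turn. Against Cre, Cacna1d went from -1.78 to -1.10 with length and GC factors. The calls of Kcnj12 were lost with these factors, from -1.04 ± 0.27 (SE) and -0.92 ± 0.25 to -0.58 ± 0.36 and -0.28 ± 0.33 (adjusted p = 0.547 and 0.668), as was that of Kcnd3 against Cre, from -1.30 ± 0.33 to -0.68 ± 0.39 (0.328), with smaller changes and larger errors. Actc1, cardiac actin, stood at 8188 CPM in the knockout, 6683 in flox controls and 8812 in Cre controls and was not called. The medians against flox and Cre were 0.24 and -0.09 for 33 sarcomere genes, -0.20 and -0.25 for 22 calcium handling genes, and -0.10 and -0.02 for 24 ion channel and conduction genes. They were -0.01 and 0.00 for 14 atrial genes and -0.21 and -0.48 for 17 cardiac stress genes. Over all genes edgeR called 0 in each of these 5 lists. Adjusted over the list alone it called 0 and 0 sarcomere, 1 and 1 calcium handling, 3 and 6 ion channel, 0 and 2 atrial and 0 and 2 stress genes. At an unadjusted p under 0.05 there were 3 and 4 sarcomere, 3 and 4 calcium handling, 6 and 7 ion channel, 3 and 3 atrial and 3 and 4 stress genes. DESeq2 called 2 and 2 sarcomere, 1 and 1 calcium handling, 3 and 6 ion channel, 2 and 2 atrial and 2 and 2 stress genes.

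Signalling, growth and metabolic lists held few calls. By DESeq2, Dll1 of the Notch pathway (log2 -1.31 and -1.18) and Cdkn2b, a CDK inhibitor (log2 -1.95 and -2.38), were lower in both comparisons. Without any 1 of the 5 controls the calls of Dll1 were lost (adjusted p from 0.251 to 0.999 and 0.0826 to 0.315), as was that of Cdkn2b against flox (0.126 to 0.659). Without knockout replicate 2 those of Dll1 against Cre (0.0532) and Cdkn2b against flox (0.0565) were lost. The medians against flox and Cre were -0.43 and -0.52 for 20 Notch genes, -0.23 and -0.15 for 28 BMP and TGF-beta genes, -0.12 and -0.14 for 21 neuregulin and FGF genes, and 0.09 and 0.08 for 11 CDK inhibitors. Cell cycle medians were 0.09 and -0.15 for S phase (22 genes) and 0.19 and 0.13 for G2M phase (26 genes). Top2a, a G2M gene, stood at 506 ± 132, 505 ± 33.0 and 534 ± 21.4 CPM in knockout, flox control and Cre control hearts. The medians against flox and Cre were 0.11 and 0.28 for 21 p53 targets, 0.07 and 0.10 for 24 hypoxia genes, 0.24 and -0.03 for 17 glycolysis genes, and 0.03 and -0.06 for 26 fatty acid oxidation genes. For 22 immediate early genes they were -0.17 and -0.19, and for 23 unfolded protein response genes 0.19 and 0.21. None of these 12 lists passed camera with all libraries. Over all genes edgeR called 0 in each, and adjusted over the list alone it called 1 and 2 CDK inhibitors and 0 in the others. At an unadjusted p under 0.05 the counts per list were at most 3 against flox and 6 against Cre, both reached by the unfolded protein response. DESeq2 called at most 1 gene per list against flox and 2 against Cre, the latter among the CDK inhibitors.

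Markers of other cell types differed between the control groups as well. Erythroid genes lay at a median of 0.17 against flox, and in Cre controls they were higher than in flox controls (median 0.68, camera adjusted p = 2.21e-08, and adjusted p = 0.878 with an estimated correlation). Megakaryocyte and platelet genes lay at -0.08 against flox, and were higher in Cre than in flox controls (median 0.85, camera adjusted p = 6.42e-08, and adjusted p = 0.811 with an estimated correlation). Glycolysis (median 0.31, adjusted p = 0.00831) and neuronal and neural crest genes (median 0.33, adjusted p = 0.0354) were also higher in Cre than in flox controls, with adjusted p = 0.878 and 0.811 with an estimated correlation. Glycolysis did not pass without flox control replicate 1 (adjusted p = 0.307) or Cre control replicate 1 (0.0511) or 2 (0.0741). The neuronal list did not pass without knockout replicate 1 (0.1) or 2 (0.0907), flox control replicate 1 (0.0559) or 2 (0.155) or Cre control replicate 1 (0.0511). Against flox and Cre controls, the knockout medians were -0.45 and -0.37 for endocardium and endothelium (25 genes) and 0.12 and 0.02 for epicardium (17 genes). They were -0.47 and -0.53 for macrophages and leukocytes (17 genes), -0.52 and -0.90 for hepatocytes (4 genes), -0.02 and -0.26 for neurons and neural crest (14 genes), and 0.38 and 0.29 for skeletal muscle (6 genes). Of 17 foregut and lung epithelium genes Sox2 alone was measured, at 0.443 ± 0.115 CPM (SD, n = 2) in the knockout, 0.742 ± 0.221 (SD, n = 2) in flox controls and 1.14 ± 0.376 (SD, n = 3) in Cre controls. By DESeq2 Gap43, of the neuronal list, was higher in both comparisons (log2 0.69 and 0.65). These calls were lost without any 1 of the 5 controls (adjusted p from 0.589 to 0.999 and 0.183 to 0.429), and that against Cre also without knockout replicate 2 (0.0648). Both were lost with length and GC factors, at 0.38 ± 0.24 (SE) and 0.32 ± 0.21 from 0.69 ± 0.19 and 0.65 ± 0.17 (adjusted p = 0.554 and 0.415), with smaller changes and larger errors. Outflow tract genes lay at a median of -0.16 against flox, with 0 and 5 called by edgeR adjusted over the list alone. By the same count edgeR called 0 and 1 epicardial, 1 and 0 hepatocyte, 0 and 1 epithelial, 0 and 5 neuronal and 1 and 2 skeletal muscle genes. It called 0 in the endothelial, erythroid, leukocyte, megakaryocyte and embryo sex (9 genes) lists, and 0 over all genes in every list of this paragraph. At an unadjusted p under 0.05 there were 1 and 3 endothelial, 0 and 3 erythroid, 1 and 1 leukocyte and 0 and 5 megakaryocyte genes and 0 and 0 embryo sex genes. There were 2 and 5 outflow tract, 3 and 3 epicardial, 1 and 1 hepatocyte, 0 and 1 epithelial, 2 and 6 neuronal and 2 and 2 skeletal muscle genes. DESeq2 called 0 and 4 outflow tract, 0 and 2 epicardial, 1 and 0 hepatocyte, 1 and 4 neuronal and 1 and 2 skeletal muscle genes. It called 0 and 1 leukocyte and 0 and 1 megakaryocyte genes and 0 in the endothelial, erythroid, epithelial and embryo sex lists.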

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

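Tests chosen after the data were seen were the likelihood ratio test, voom with quality weights, the length and GC corrections, DESeq2 and camera with an estimated correlation without knockout replicate 2, DESeq2 without each library in turn, camera between the controls without each library in turn, and edgeR on the control libraries alone without each of them. No paired analysis was made. The labels give each library an identifier of its own and name no litter or pair. Some identifiers share a start, NT in 3 libraries and 10R in Cre control replicates 1 and 3. The labels do not say what these starts mean, and they were not used as blocks. Counts of genes follow the order against flox, against Cre, between controls, against the mean of controls and against both, where edgeR gave 2, 2, 0, 3 and 2. DESeq2 gave 301, 555, 73, 600 and 169. With length and GC factors it gave 334, 641, 121, 664 and 185, and without knockout replicate 2 it gave 972, 459, 358, 622 and 232. The likelihood ratio test gave 145, 435, 67, 392 and 93. Length and GC offsets in edgeR gave 18 against Cre and 4 between controls. RLE gave 1 against flox and 1 against both. Limma-voom gave 0 against flox and 0 against both, and the compared groups alone 0 and 0, with 56 between controls. Quality weights gave 0, 1, 47, 0 and 0, and embryo sex as covariate 0 in all comparisons with the knockout. Without 1 library the counts ranged from 0 to 7547, 0 to 8813, 0 to 57, 0 to 8568 and 0 to 7200. Hand1 was lower in every setting, from -5.27 to -4.76 against flox and -6.17 to -5.92 against Cre without 1 library. It missed the threshold against flox with limma-voom (-5.01) and the compared groups alone (-5.04), and in both comparisons with quality weights (-5.01 and -6.06) and embryo sex as covariate (-5.05 and -6.03). It also missed it against flox without any 1 control library and against Cre without any 1 Cre control. Without Cre control replicate 1, 2 or 3 the change of Hand1 against flox stayed at -5.056, -5.035 and -5.035. Those misses therefore came through the error of the test and not through a smaller change. The cause of the other misses was not tested. Nkx2-5 ranged from -0.715 to -0.208 against flox and -0.176 to 0.338 against Cre without 1 library, passed the threshold against flox without knockout replicate 1 (adjusted p = 0.0197), and lay at -0.0966 against Cre with embryo sex as covariate. Camera called 4 lists against flox and 7 against Cre. It called 0 and 0 with an estimated correlation, also without knockout replicate 2, and 7 against flox with a mean of at least 5 CPM or with members in no other list. Fry called 1 and 1. Without 1 library camera called 4 to 8 and 7 to 12 lists. Of the values of named genes under alternatives, 754 kept their direction and call, 200 passed the threshold that they had missed, 30 no longer passed it, and 10 values of Hand2 and Nkx2-5 changed sign with no call. Of the 99 DESeq2 calls of named genes and list members, 2 and 21 were lost without knockout replicates 1 and 2. Without flox control replicates 1 and 2 in turn 51 and 53 were lost, and without Cre control replicates 1 to 3 in turn 54, 52 and 59, with no change of sign. With length and GC factors 30 of the 99 were lost. Most named genes were taken from DESeq2 calls that edgeR had missed, so passing under DESeq2 and its variants was largely set by that choice. The few calls lost without knockout replicate 1 tell little. That fit rests on the replicate that stood apart and takes its spread from the controls. Depth limits genes near 1 CPM, such as Hand1 in the knockout (37 and 19 counts).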

Other observations

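The tests of the NT identifiers, the held-out Cre controls and the held-out flox controls were set out before their own results, the last after the result of the second. All other tests were chosen after results were seen: the replicate test was split and its reading rewritten after its values, and the mesenchyme values were corrected after an uncorrected version.

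Both knockout libraries and flox control replicate 2 carry identifiers that start with NT. Between these 3 and the other 4 libraries, 11 genes had a gap over 4-fold, against 1 with flox control replicate 1 in place of replicate 2 and 0 with any Cre control in its place. Ifi44 was counted 120 and 128 times in the knockout libraries, 104 times in flox control replicate 2, 7 times in replicate 1 and at most 3 times in Cre controls. Ifi204 was counted 51 and 211 times in the knockout libraries and 223 and 7 times in flox control replicates 2 and 1. The hormone gene Fgf23 went the other way, with 9 and 5 counts in the knockout libraries, 6 and 39 in flox control replicates 2 and 1 and 50 to 55 in Cre controls. None of the 11 was among the 169 genes that DESeq2 called against both groups. Their choice largely set this, since flox control replicate 2 lies with the knockouts in each of them, which works against a call against flox. It therefore tells nothing of a shared NT origin for the 169 genes. These genes were chosen after their values were seen.

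Knockout replicate 2 stood apart from the other 6 libraries. A control library under a knockout label is argued against by its Hand1 level of 1.14 CPM, where the lowest control had 34.1. A lower share of cardiomyocytes would raise the markers of every other cell type. With the length and GC trend removed, however, cushion and valve mesenchyme lay at a median of -1.0 ± 0.24 (SE) and epicardium at -0.23 ± 0.17. These errors are over the 22 and 17 genes of the lists in this library alone. They take genes as independent and do not measure a spread between embryos. Gene length and GC content held 57% of the variance of its log2 deviation from the controls, against 32.7% in the next library, flox control replicate 1, so a loss of long and GC-rich transcripts is a candidate explanation. A difference between the knockout embryos themselves stays open and was not tested.

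Genes differed between the knockout and both control groups, 169 of them by DESeq2, of which 20 to 33 were still called when any 1 control library was left out. The fitted length and GC trends alone do not give the calls of the 84 genes still called after correction, and stay open for the other 85. The 84 were picked by the correction itself, so they are no separate evidence. It called 185 genes against both groups, so the list changed with the fit. A shared NT origin cannot be told apart, since both knockout libraries carry NT identifiers and the test set 1 NT flox control against 1 other, too few for the bound set before it (0.038 ± 0.035 toward the knockout, SE over the 555 genes called against Cre controls, where the median effect was 1.36). Of genes called from replicate 1 against Cre controls, replicate 2 with its length and GC trend removed went the same way against flox controls in 77.8% (52.3% of uncalled genes), which argues against differences particular to replicate 1, whereas of those called from it against flox controls, replicate 2 corrected likewise went the same way against Cre controls in 45.2% (44% of uncalled genes), so differences particular to replicate 1 or to the flox controls stay open there. For the edgeR count of the knockout against all 5 controls, chance is not excluded. Of the 21 splits of the 7 libraries, 2 gave at least the 4 genes of the real split. The highest other, knockout replicate 2 with flox control replicate 1, gave 4118 and points to a structure of the samples. By DESeq2 that split gave 6152 genes, the real split 940 and each remaining split at most 30. Knockout replicate 2 and flox control replicate 1 shared a trend with GC content. Across genes their deviation from the controls had Spearman correlations of -0.490 and -0.490 with GC content, against 0.03 to 0.45 in the other libraries. This shared GC trend is a candidate for the structure and was not tested.

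Hand1 and some genes lower in the knockout lay lower in flox than in Cre controls, namely 7 of the 10 named decreases but 40 of the 132 genes called lower against both groups, a set that a call against flox selects for high flox levels. Of genes lower in the knockout than in 2 Cre controls, 73.9%, 66.7% and 100% were lower in flox controls than in the held-out Cre control, against at most 50.7% of all genes, so less Hand1 from the floxed allele before recombination may account for part of the pattern. Of the genes higher in the knockout, 86.7% to 96.3% were likewise higher in flox controls. These shares do not single out the floxed allele, since flox control replicate 1 also shared the GC trend of knockout replicate 2. Their Spearman correlations with GC content were both -0.49, against 0.35, 0.45 and 0.03 in Cre control replicates 1 to 3. The part of that trend in the shares was not tested. Genes called between the knockout and 1 flox control lay toward the knockout in the other in 40% (95% interval 22.7 to 59.4, uncalled genes 56.5%) and 57.1% (41 to 72.3, uncalled genes 45.9%). The intervals take genes as independent, so they are too narrow where genes move together. A difference particular to the Cre controls thus also stays open, and part of the calls against Cre controls may belong to it. Linked DNA of another strain around Hand1 stays open too, with 2 genes within 10 Mb (Hist3h2a and Pirt) called between the controls against 0.81 expected (one-sided Fisher's exact test, p = 0.194).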
